A study of Homo sapiens with 6 samples.

How the data were processed

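RNA from MCF7 cells was measured by RNA sequencing in 6 libraries, 3 per group, each made from 1.0 µg of total RNA that had been extracted with TRIzol, using the NEBNext Ultra RNA kit, per the labels' protocols. The deposited values are raw counts of reads per gene symbol, not normalized, with one column per library. The reads were aligned and counted with HISAT2 and featureCounts against hg38, per the submitters' processing notes. Versions, the annotation release, the strand setting, the handling of reads with several matches and any filter are not given in the sources used here. The table held 30417 gene symbols and no gene at 0 in all libraries. Symbols are the identifiers in the table. They were matched to GENCODE release 29 on GRCh38 for position, gene type, GC content and transcript length, and 29004 (95.35%) matched a single gene, 699 of them through a gene ID; 67 symbols that named several genes and 1346 with no match were left without annotation.

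Groups were taken from the labels, and the 3 replicates of each were treated as separate samples. Pairs of libraries of 1 group differed by more than sampling noise, so no library was counted as a repeat of another. Library totals were 15742772 to 18284393 reads. In simulated counts for control against glucose withdrawal, drawn for 14507 genes from the means and library sizes of the data with 200 genes changed, the test recovered 59.7% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 3-fold, and 8.33% of 180 calls were unchanged genes. The simulated changed list was called and 0 of 34 unchanged lists were, by limma camera. Each gene was drawn independently in these counts, so they do not show how often lists of correlated genes are called wrongly. A simulated GC trend gave 5053 calls, and 0 after the offset for GC content. It was put alike into the 3 withdrawal libraries, steeper than in the data, with no gene truly changed. It therefore does not show whether the offset spares true changes linked to GC content.

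Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14718. Counts were scaled by TMM, with factors of 0.985 to 1.01, and tested with the edgeR quasi-likelihood functions glmQLFit and glmQLFTest in a model with group as its single term. The common biological coefficient of variation was 0.0985. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p below 0.05. Log2 fold changes are withdrawal against control, and CPM are TMM-normalised. Standard errors were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. "Rose" and "fell" are used for genes that passed. Single measures per library were compared with a two-sided exact permutation test, which cannot go below 0.10 with 3 against 3, so no such measure could pass 0.05.

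The 36 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested genes (35) were tested with limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Counts adjusted over the list alone use Benjamini-Hochberg on the list's members only. Genes were named if they were among the 8 largest rises or the 8 largest falls with an adjusted p below 0.05, a mean of at least 5 CPM and no overlap between groups. Genes with a clone name in place of a gene symbol, Y-linked genes and XIST were passed over in this ranking. TXNIP, ARRDC4, DDIT3, ASNS, TRIB3, HSPA5, SLC2A1, HK2, ESR1 and CDKN1A were named whatever their values, as were the 3 members with the smallest p of each list described. Near-identical gene copies can divide reads, and overlapping genes cannot be separated without strand, so such genes are given as uncertain.

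The alternatives were DESeq2 size factors, library totals alone, no low-count filter, a stricter filter (5 CPM in 3 libraries), the DESeq2 Wald test, limma-voom, a replicate block, each library left out in turn, mitochondrial genes left out, an estimated correlation, and a prior count of 0.5. An offset per library for GC content, another for transcript length, and leaving out structural with mitochondrial RNA were added after the data were seen. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.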

Results

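MCF7 is an oestrogen-receptor-positive luminal breast cancer cell line that grows as an adherent epithelial layer. RNA sequencing gave read counts per gene for 6 libraries, 3 from control cells and 3 from cells deprived of glucose, and the labels call the replicates of each group biological. The line was maintained in DMEM with 10% serum, and all cells were plated 2 days before the experiment. Control cells had a single medium change, 4 hours before harvest. The withdrawal cells had the same 4-hour change and then a further change into DMEM lacking glucose, for a time that the labels do not state, so medium handling and glucose differed together between the groups. The labels do not say whether the medium lacking glucose held serum or other supplements. The libraries held 15742772 to 18284393 counted reads. The control libraries held 16001877, 17970568 and 17668658 reads, and the withdrawal libraries 15742772, 18284393 and 16573492.

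The comparison asked which transcripts changed when glucose was taken away, a withdrawal that the series title calls short-term. The cytochrome P450 genes CYP1A1 and CYP1B1, textbook targets of the aryl hydrocarbon receptor, were among the strongest risers. CYP1A1 went from 27.6 ± 3.11 CPM to 533 ± 36.4 CPM (SD, n = 3), a 19.3-fold rise, and CYP1B1 from 151 ± 20.2 CPM to 980 ± 162 CPM, a 6.51-fold rise. Stress-response transcription factors rose with them, DDIT3 (CHOP) 5.13-fold and ATF3 4.43-fold, as did CHAC1, a glutathione-degrading enzyme, at 7.28-fold, and HMOX1, haem oxygenase, at 4.19-fold. TXNIP, the thioredoxin-interacting protein whose transcription follows glucose supply, fell from 239.6 ± 9.47 CPM to 35 ± 1.23 CPM, a 6.84-fold drop. Its relative ARRDC4 fell 3.64-fold, and PFKFB4, a bifunctional regulator of glycolytic flux, fell 4.36-fold.

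On the log2 scale CYP1A1 rose by 4.27 ± 0.11 (SE; adjusted p = 9.22e-15, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, used for every gene below). CHAC1 rose by 2.86 ± 0.13 (adjusted p = 7.68e-11), CYP1B1 by 2.70 ± 0.12 (7.68e-11), DDIT3 by 2.36 ± 0.15 (9.76e-09), ATF3 by 2.15 ± 0.16 (1.23e-07) and HMOX1 by 2.07 ± 0.10 (1.11e-10). The chemokine gene CXCL8 rose 5.07-fold from a low level, 1.80 ± 0.195 CPM in control cells against 9.16 ± 1.96 CPM after withdrawal. The antisense transcript CYP1B1-AS1 rose 4.93-fold, from 1.88 ± 0.544 CPM to 9.39 ± 1.79 CPM, but it overlaps CYP1B1 on the opposite strand, and the strand setting of the counting is not given in the sources used here, so reads of this pair cannot be told apart. Among the falls, TXNIP changed by -2.77 ± 0.09 (adjusted p = 4.31e-13), PFKFB4 by -2.13 ± 0.15 (3.89e-08) and ARRDC4 by -1.86 ± 0.12 (2.18e-08). The neurexophilin gene NXPH3 fell 2.50-fold (adjusted p = 1.65e-06) and the liprin gene PPFIA4 2.83-fold (7.76e-05). LRFN1 fell 2.67-fold, TMEM121 2.41-fold and INAFM2 2.29-fold, with adjusted p of 6.44e-05, 1.99e-05 and 7.57e-05. Each of these 16 genes had every withdrawal library on one side of every control library, which the rule for naming them required.

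The genes lie, by GENCODE release 29 on GRCh38, at these places, and all but CYP1B1-AS1 are annotated as protein-coding. CYP1A1 spans bases 74719542 to 74725610 of chromosome 15, on the minus strand, and CHAC1 bases 40952962 to 40956519 of the same chromosome, on the plus strand. ARRDC4 lies on that chromosome too, at 97960698 to 97973838, plus strand. CYP1B1 occupies 38066973 to 38109902 of chromosome 2, minus strand, and CYP1B1-AS1 occupies 38073447 to 38231651, plus strand. DDIT3 lies at 57516588 to 57521737 of chromosome 12, minus strand, and HMOX1 at 35380361 to 35394214 of chromosome 22, plus strand. TXNIP lies at 145992435 to 145996600 of chromosome 1, minus strand, and PFKFB4 at 48517684 to 48562015 of chromosome 3, minus strand.

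**Figure D1:**
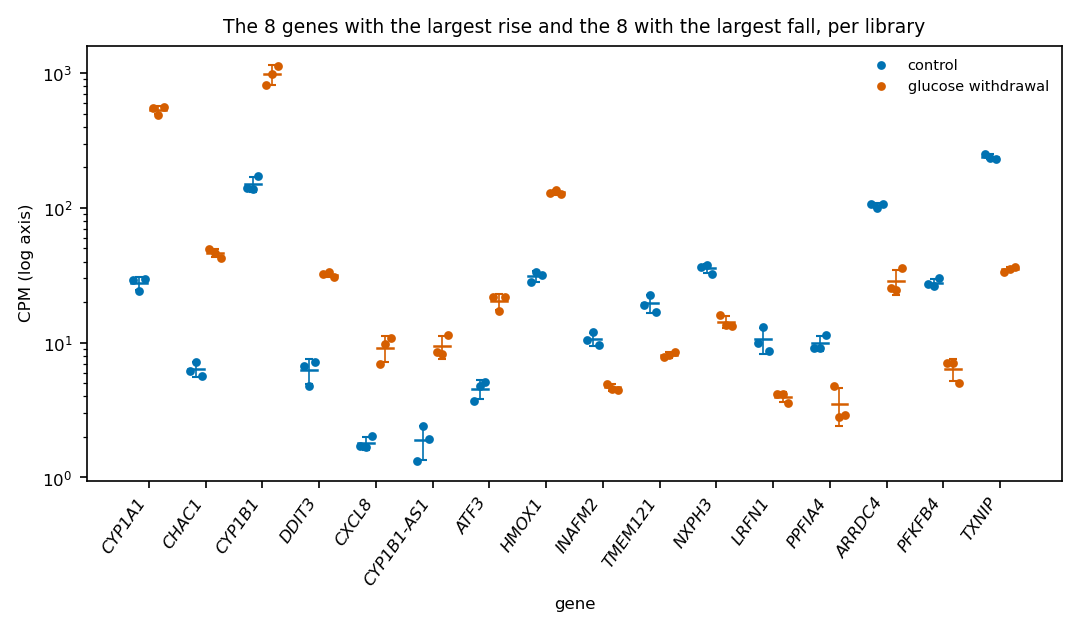
TMM-normalised expression (CPM, log axis) in each library for the 8 genes with the largest rise and the 8 with the largest fall among those meeting the rule for named genes; points are single libraries, long horizontal lines group means and bars 1 SD (n = 3 per group). That rule required the 3 withdrawal libraries to lie wholly above or wholly below the 3 control libraries. CYP1A1 stood at 27.6 CPM in control against 533 CPM in withdrawal libraries, and TXNIP at 239.6 against 35 CPM.

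Across 14718 genes tested, 894 were higher and 842 lower after withdrawal, 11.8% of those tested. Of these, 164 were at least 2-fold higher and 68 at least 2-fold lower, so most changes were small. The median log2 fold change was 0.58 among the genes called higher and -0.50 among those called lower. Control and withdrawal libraries did not overlap for 1713 of the 1736 called genes, against 30.0% of all tested genes and 10% by chance for 3 against 3. The test itself favours genes without overlap, so the share among called genes largely restates the calls. The counts rested in part on the control libraries. Without control library 1 the test called 447 higher and 445 lower, without control library 2 it called 410 and 291, and without control library 3 it called 574 and 435. The count at least 2-fold lower was 38 without control library 2.

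**Figure D2:**
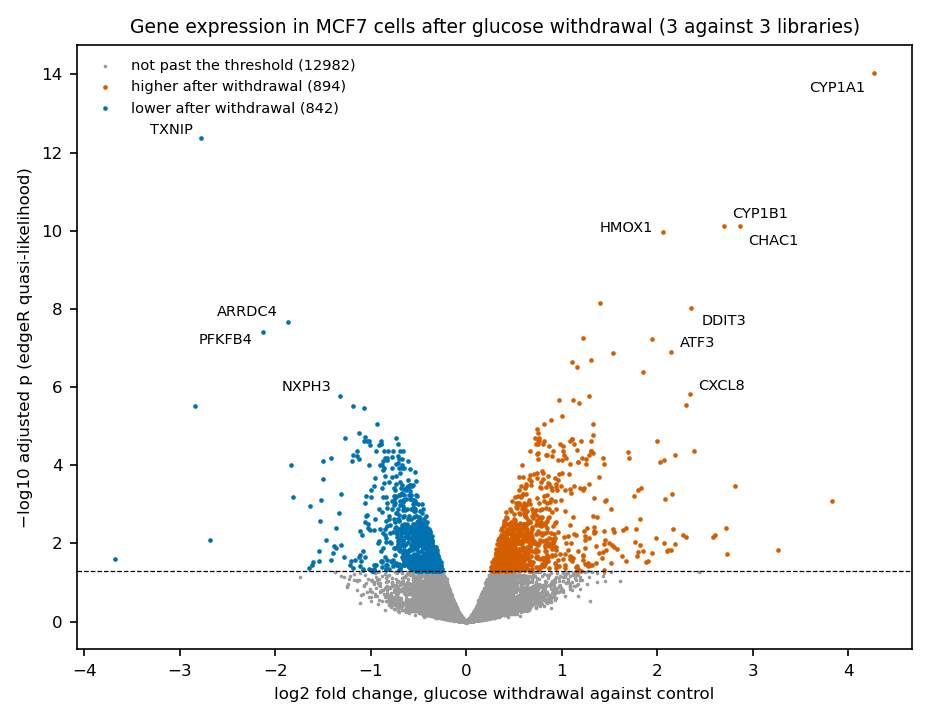
Each point is 1 of 14718 tested genes, with its log2 fold change (glucose withdrawal against control, 3 libraries each) on the horizontal axis and the -log10 of its edgeR adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05. The 894 genes called higher and 842 called lower are coloured, and CYP1A1 and TXNIP have the smallest adjusted p on their sides of the plot.

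Genes of the integrated stress response, which ATF4 switches on when amino acids run short or proteins misfold, rose as a group. Of 22 members tested, 16 rose, 1 fell and 5 did not pass, and adjusted over the list alone 17 rose and 1 fell. The list passed limma's camera test at an adjusted p of 3.39e-13 with a preset correlation, and had an adjusted p = 0.0596 with an estimated correlation. CHAC1, DDIT3 and ATF3 led it, and TRIB3, a pseudokinase induced by ATF4 and CHOP, rose by 0.59 ± 0.08 on the log2 scale (adjusted p = 9.71e-05). ASNS, asparagine synthetase, rose by 0.94 ± 0.23 (adjusted p = 0.0120) at a low level, from 1.70 CPM in control to 3.25 CPM in withdrawal libraries. Its call ended without control library 2 (0.0679) or control library 3 (0.0514). The member that fell was ATF5, at -0.32, named after its value was seen; its call ended without control library 1 (0.123), 2 (0.159) or 3 (0.0839).

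Amino acid transporters and aminoacyl-tRNA synthetases moved the same way, with 8 of 21 members rising, 0 falling and 13 not passing, and 11 rising adjusted over the list alone (camera adjusted p = 4.91e-06; adjusted p = 0.147 with an estimated correlation). SLC7A11, the cystine importer, rose by 1.95 ± 0.14 (adjusted p = 5.89e-08), while SLC7A5 and SLC3A2, the light and heavy chains of the large neutral amino acid transporter, each rose by 0.40 ± 0.08. In the serine, glycine and one-carbon list, 3 of 12 members rose, 0 fell and 9 did not pass, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0386; adjusted p = 0.300 with an estimated correlation). Those 3 were the mitochondrial folate enzyme MTHFD2 (0.55 ± 0.08) and the serine synthesis enzymes PSAT1 (0.68 ± 0.10) and PHGDH (0.36 ± 0.09). PHGDH lost its call without control library 1 (adjusted p = 0.0946), 2 (0.0545) or 3 (0.0739). The serine list lost its call with the stricter low-count filter (0.0542), with the replicate block (0.0767), and without control library 3 (0.0641), withdrawal library 1 (0.176) or withdrawal library 2 (0.0555).

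ER chaperones and ER-stress targets, the unfolded protein response arm under XBP1 and ATF6, did not pass as a list (camera adjusted p = 0.0506). Of 23 members 3 rose, 1 fell and 19 did not pass, and adjusted over the list alone 5 rose and 2 fell. HERPUD1, an ER-associated degradation factor, rose by 0.89 ± 0.09, the co-chaperone gene DNAJB9 by 0.81 ± 0.11 and HSPA5, the ER chaperone BiP, by 0.42 ± 0.08 (adjusted p = 0.00153). The member that fell was SYVN1 (-0.35; named after its value was seen), and without each library but withdrawal library 3 its adjusted p was 0.0851 (control 1), 0.165 (control 2), 0.107 (control 3), 0.0686 (withdrawal 1) and 0.0651 (withdrawal 2). The list passed the threshold with library totals alone (0.0477), with mitochondrial genes left out (0.0432), with structural and mitochondrial RNA left out (0.0430), with a prior count of 0.5 (0.04999), with the stricter low-count filter (0.0313) and without withdrawal library 3 (0.0438).

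Targets of the glucose-sensing factors MondoA and ChREBP fell in 4 of 10 cases, with 0 rising and 6 not passing, and 4 fell adjusted over the list alone (camera adjusted p = 0.00677; adjusted p = 0.346 with an estimated correlation). After TXNIP and ARRDC4 came PFKFB3, another regulator of glycolytic flux, at -0.71 ± 0.08 (adjusted p = 2.89e-05). KLF10, named after its value was seen, changed by -0.41 ± 0.09, and its adjusted p was 0.0507 without control library 3. Of 23 glycolysis and glucose uptake genes 6 fell, 1 rose and 16 did not pass, and adjusted over the list alone 9 fell and 2 rose (camera adjusted p = 0.00580; adjusted p = 0.443 with an estimated correlation). PFKFB4 was followed by the enolase gene ENO2 (-0.66 ± 0.11) and the hexokinase gene HK1 (-0.46 ± 0.08), and the riser was PFKFB2 (0.56 ± 0.12), named after its value was seen. The glucose transporter gene SLC2A1 (-0.16 ± 0.08, adjusted p = 0.238) and the hexokinase gene HK2 (-0.14 ± 0.08, adjusted p = 0.321) did not pass. With an offset for GC content, chosen after the data were seen, the glycolysis list no longer passed (adjusted p = 0.222).

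Hypoxia-inducible factor targets fell in 9 of 21 cases with 0 rising and 12 not passing, and in 11 adjusted over the list alone (camera adjusted p = 7.60e-05; adjusted p = 0.300 with an estimated correlation). The leading members were PPFIA4 (-1.50 ± 0.20), the oxygen-sensing prolyl hydroxylase gene EGLN3 (-0.63 ± 0.11) and the mitophagy receptor gene BNIP3 (-0.42 ± 0.09), whose call ended without control library 3 (adjusted p = 0.0589). In the list for fasting, fatty acid oxidation and ketogenesis, 4 of 19 members fell, 0 rose and 15 did not pass, with 4 falling adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.254 with an estimated correlation). Its fallers were the secreted lipase inhibitor gene ANGPTL4 (-0.83 ± 0.11, adjusted p = 7.14e-05), the ketone body enzyme gene BDH1 (-0.45 ± 0.12), the lipid droplet coat gene PLIN2 (-0.63 ± 0.18) and, named after its value was seen, the pyruvate dehydrogenase kinase gene PDK2 (-0.47 ± 0.14). None of them encodes a step of fatty acid beta-oxidation itself. The list did not pass without control library 3 (0.0700) or withdrawal library 1 (0.0554). BDH1 lost its call without control library 1 (0.0805), 2 (0.132) or 3 (0.0572). PLIN2 lost it without control library 1 (0.0669), 2 (0.105) or 3 (0.108), or withdrawal library 1 (0.0691) or 3 (0.0646). PDK2 lost it without control library 1 (0.135), 2 (0.113) or 3 (0.0890), or withdrawal library 2 (0.0812) or 3 (0.0538).

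Genes of the NRF2 antioxidant response rose in 7 of 24 cases, with 0 falling and 17 not passing, and 7 rose adjusted over the list alone (camera adjusted p = 0.00677; adjusted p = 0.300 with an estimated correlation). HMOX1, SLC7A11 and OSGIN1 (1.41 ± 0.08, adjusted p = 7.16e-09) led the list, whose median was 0.07. AP-1 and immediate-early genes, the first genes to respond to serum and stress signals, rose in 14 of 27 cases. FOS alone fell, 12 did not pass, and adjusted over the list alone 17 rose and 2 fell (camera adjusted p = 2.15e-07; adjusted p = 0.147 with an estimated correlation). The phosphatase gene DUSP1 rose by 1.30 ± 0.10, the orphan receptor gene NR4A1 by 1.29 ± 0.12 and JUN by 0.76 ± 0.09, whereas FOS, named after its value was seen, changed by -0.54 ± 0.10. NF-kB and cytokine genes rose in 8 of 16 cases, with 0 falling and 8 not passing, and 9 rose adjusted over the list alone (camera adjusted p = 4.91e-06; adjusted p = 0.165 with an estimated correlation). With CXCL8, the feedback inhibitor gene TNFAIP3 rose by 0.83 ± 0.13 and the NF-kB subunit gene RELB by 0.69 ± 0.12.

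Ribosome biogenesis and MYC targets rose in 7 of 34 cases, with 0 falling and 27 not passing, and 7 rose adjusted over the list alone (camera adjusted p = 0.00677; adjusted p = 0.300 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, rose by 0.57 ± 0.09, the nucleolar helicase gene DDX21 by 0.46 ± 0.11 and the pre-ribosome export factor gene RRP12 by 0.38 ± 0.09. DDX21 lost its call without control library 2 (adjusted p = 0.0842) and RRP12 without control library 1 (0.0718). In the circadian clock list 3 of 17 genes rose, 0 fell and 14 did not pass, and 4 rose adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.254 with an estimated correlation). The REV-ERB gene NR1D2 rose by 1.08 ± 0.12 (adjusted p = 2.39e-05), CRY1 by 0.43 ± 0.13 and PER2 by 0.42 ± 0.13. CRY1 lost its call without control library 1 (0.244), 2 (0.116) or 3 (0.0527) and without withdrawal library 1 (0.0502) or 3 (0.128). PER2 lost it without control library 1 (0.126), 2 (0.0958) or 3 (0.158) and without withdrawal library 1 (0.122) or 3 (0.123).

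Oestrogen receptor targets fell in 6 of 29 cases, rose in 2 and did not pass in 21, and adjusted over the list alone 9 fell and 3 rose (camera adjusted p = 0.0361; adjusted p = 0.316 with an estimated correlation). CCND1, cyclin D1, fell from 1564 to 1081 CPM (-0.53 ± 0.08, adjusted p = 1.49e-04), while SLC7A5 and the growth factor gene AREG rose by 0.40 ± 0.08 each. The list did not pass with the GC offset (0.325), with the stricter low-count filter (0.0536), or without control library 1 (0.0768) or withdrawal library 1 (0.0567). ESR1, the oestrogen receptor gene itself, fell by 0.47 ± 0.09 (adjusted p = 0.00282). It belongs to the luminal identity list, where 5 of 21 members fell, 1 rose and 15 did not pass, by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0799). GATA3, a luminal lineage transcription factor, changed by -0.53 ± 0.08 and the androgen receptor gene AR by -0.71 ± 0.13. The other fallers were SPDEF (-0.39) and KRT19 (-0.36), and the riser was TFAP2A (0.47), all named after their values were seen. SPDEF (adjusted p = 0.0570) and KRT19 (0.0779) lost their calls without control library 2, and TFAP2A lost its call without control library 1 (0.105), control library 2 (0.0875) or withdrawal library 3 (0.0592).

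**Figure D3:**
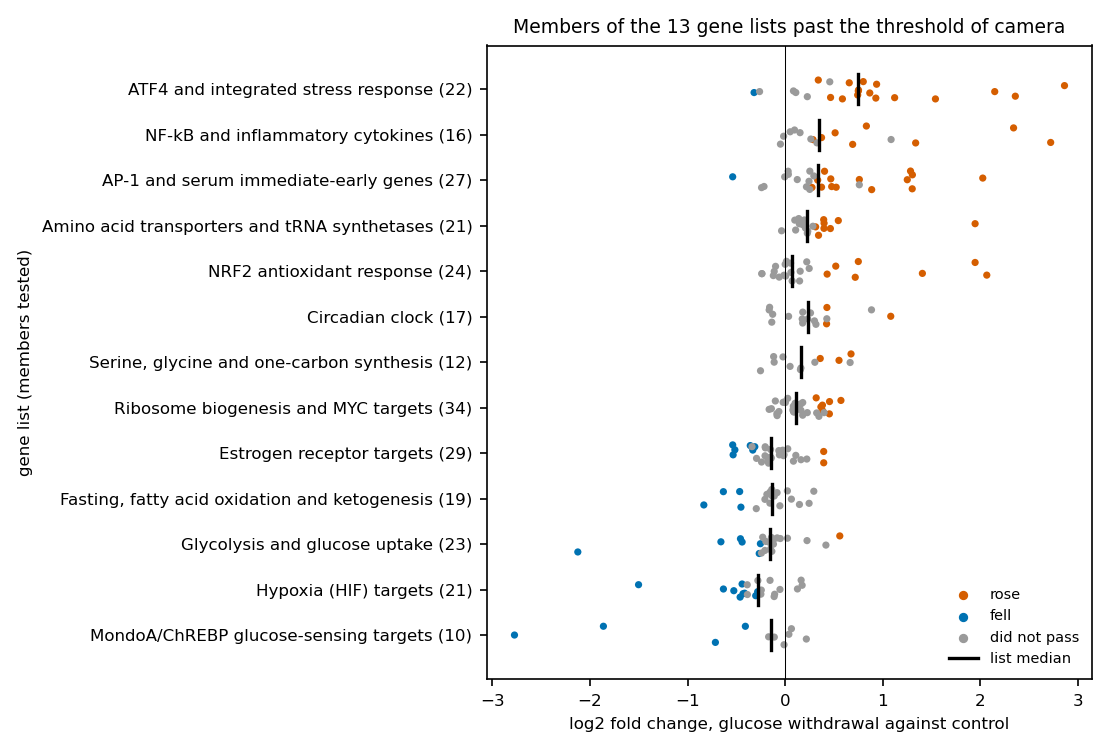
Log2 fold change (glucose withdrawal against control, 3 libraries each) of every tested member of the 13 gene lists past the camera threshold with a preset correlation; points are genes, coloured by whether they rose, fell or did not pass edgeR's test, black bars are list medians, and the number tested is in brackets. The medians run from -0.28 for hypoxia targets to 0.75 for the integrated stress response, and with an estimated correlation 0 of these lists passed.

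Of 35 lists tested, 8 were higher and 5 lower by camera with a preset correlation. With an estimated correlation 0 passed after adjustment and 6 had an unadjusted p under 0.05. The rotation test fry called 11 lists higher and 6 lower, the 13 above included, and 28 lists passed its mixed test. Its directional p tests whether the genes of a list move, on balance, one way and its mixed p whether they change in either direction, and neither sets a list against other genes.

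The remaining metabolic lists did not pass camera. Cholesterol synthesis had 4 of 24 members rising and 0 falling (7 and 0 adjusted over the list alone; camera adjusted p = 0.184), among them the sterol sensor gene INSIG1 (0.45 ± 0.09), the LDL receptor gene LDLR (0.46 ± 0.10) and the rate-limiting enzyme gene HMGCR (0.31 ± 0.09). The remaining riser, IDI1 (0.33), was named after its value was seen. HMGCR lost its call without control library 1 (0.0922), 2 (0.137) or 3 (0.133), IDI1 without those (0.0875, 0.153 and 0.120) or withdrawal library 2 (0.0951), and the list passed without withdrawal library 3 (0.0438). Fatty acid synthesis had 1 of 15 rising, GPAM (0.51 ± 0.13), and 1 falling, FASN (-0.35 ± 0.09), with the same counts adjusted over the list alone (0.952); its median was -0.04 and its mean 0.02. FASN lost its call without control library 1 (0.0571) or 2 (0.119), and GPAM without control library 1 (0.0690), 2 (0.0939) or 3 (0.0546) or withdrawal library 3 (0.0603). The acyl-CoA synthetase gene ACSL3 (0.30) did not pass, but passed with no low-count filter (0.0448) and without withdrawal library 1 (0.0119). The TCA cycle had 1 of 24 falling and 0 rising (0 and 0 adjusted over the list alone; 0.320), nuclear-encoded oxidative phosphorylation 1 of 39 rising and 0 falling (0 and 0; 0.432) and the pentose phosphate pathway 0 of 9 changing either way (0 and 0; 0.739), with PRPS1 (0.29), RPIA (0.24) and G6PD (-0.11) nearest to the threshold. The TCA member was SDHA (-0.35 ± 0.11), whose call ended without control library 1 (0.185), 2 (0.132) or 3 (0.173) or withdrawal library 1 (0.0746) or 2 (0.0779), and also with library totals alone (0.0551), mitochondrial genes left out (0.0542), structural and mitochondrial RNA left out (0.0543), no low-count filter (0.0917), the stricter filter (0.0532) and the replicate block (0.0590). IDH3B (-0.27) and SUCLG2 (0.26) did not pass. The oxidative phosphorylation member was UQCRB (0.33 ± 0.10), whose call ended without control library 1 (0.120), 2 (0.0972) or 3 (0.145) or withdrawal library 2 (0.111), while ATP5F1A (-0.15) and ATP5F1E (0.23) did not pass, except ATP5F1E without withdrawal library 3 (0.0119). In the hexosamine and N-glycan list 1 of 22 rose and 2 fell (2 and 2 adjusted over the list alone; 0.746), with the O-GlcNAc transferase gene OGT at -0.47 ± 0.10 and the opposing hydrolase gene OGA at 0.35 ± 0.09, a call that ended without control library 1 (0.113) or 2 (0.139). MPI (-0.35 ± 0.10) also fell, and lost its call without control library 1 (0.169), 2 (0.0835) or 3 (0.0969) or withdrawal library 2 (0.0592). Autophagy and lysosome genes split, 3 of 31 rising and 4 falling by either adjustment, adjusted over the list alone included (0.542). The folliculin gene FLCN and its partner gene FNIP1 rose by 0.61 ± 0.11 and 1.13 ± 0.13, and the autophagy kinase gene ULK1 changed by -0.52 ± 0.09. The other members past the test, named after their values were seen, were SQSTM1 (0.37), TFEB (-1.53), ATG2A (-0.49) and ATG9A (-0.40). SQSTM1 lost its call without control library 1 (0.0511), and ATG9A without control library 1 (0.0853), 2 (0.181) or 3 (0.0748) or withdrawal library 2 (0.0911). The oxidative phosphorylation list, whose median was -0.04 with all libraries, passed as lower without withdrawal library 2 (camera adjusted p = 0.0290).

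Growth and stress lists outside those above did not pass camera either. Among p53 targets 6 of 22 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.187), led by the growth arrest gene GADD45A (1.11 ± 0.13), MDM2 (0.48 ± 0.10) and the exonuclease gene AEN (0.33 ± 0.08), whose call ended without control library 1 (0.0931), 2 (0.0526) or 3 (0.0915) or withdrawal library 1 (0.0541). The cell cycle inhibitor gene CDKN1A, at 0.24 ± 0.08, did not pass (adjusted p = 0.0688), but passed with the stricter filter (0.0412) and without withdrawal library 2 (0.0391) or 3 (0.0202). FOXO targets had 5 of 22 rising and 1 falling (7 and 3 adjusted over the list alone; 0.225), including GADD45A, KLF6 (0.74 ± 0.11) and the insulin receptor substrate gene IRS2 (0.62 ± 0.10). The faller was CITED2 (-0.43), and FOXO3 (0.43) and BCL2L11 (0.51) completed the risers, all named after their values were seen. CITED2 lost its call without control library 3 (0.0631) and FOXO3 without control library 2 (0.0860). Among heat shock genes 0 of 19 rose and 2 fell (0 and 2 adjusted over the list alone; 0.225), the constitutive chaperone gene HSPA8 (-0.58 ± 0.08) and HSPA1A (-0.55 ± 0.10), which shares reads with its near-identical copy HSPA1B (-0.26, past the threshold only without withdrawal library 2, 0.0297) and is uncertain for that reason. S-phase genes had 2 of 32 falling and 0 rising (2 and 0 adjusted over the list alone; 0.124), the cyclin E gene CCNE1 (-0.91 ± 0.16) and the thymidylate synthase gene TYMS (-0.69 ± 0.14), while the polymerase gene POLD1 (-0.30) did not pass. Mitosis genes had 2 of 31 falling and 0 rising (1 and 0 adjusted over the list alone; 0.184), the kinetochore motor gene CENPE (-0.95 ± 0.18) and PLK1 (-0.28 ± 0.08). PLK1 lost its call without control library 1 (0.185), 2 (0.210) or 3 (0.0956) or withdrawal library 2 (0.0664). CDC20 (-0.29, adjusted p = 0.0547) passed with the DESeq2 Wald test (0.0407), the replicate block (0.0454) and without withdrawal library 1 (0.0338). Replication-dependent histone genes, which resemble one another closely in sequence, had 2 of 17 rising and 0 falling (4 and 0 adjusted over the list alone; 0.0761), and the list passed without control library 1 (0.0358). H2AC11 rose by 0.84 ± 0.16 and H2BC11 by 0.68 ± 0.18, which lost its call without control library 1 (0.0544), 2 (0.0687) or 3 (0.0991) or withdrawal library 1 (0.0546). H2AC6 (0.29, adjusted p = 0.0570) passed with the DESeq2 Wald test (0.0498), the stricter filter (0.0363), structural and mitochondrial RNA left out (0.0495) and without withdrawal library 3 (0.0384). Interferon-stimulated genes had 0 of 22 changing (0 and 0 adjusted over the list alone; 0.527), with RSAD2 (1.43), PSMB9 (0.79) and STAT1 (0.27) nearest to the threshold. PSMB9 passed with no low-count filter (0.0423), the replicate block (0.0399) and the GC offset (0.0465) and without withdrawal library 3 (0.0434), and STAT1 without withdrawal library 2 (0.0187).

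Markers of other cell types did not pass as lists. Fibroblast markers had 0 of 6 changing (0 adjusted over the list alone; camera adjusted p = 0.306), and VIM stood at 0.316 CPM in control and 0.872 CPM in withdrawal libraries, all 3 of these above all 3 controls (log2 fold change 1.46, adjusted p = 0.0909), and passed with the replicate block (0.0487). TAGLN (0.36) and FN1 (-0.15) followed it. Basal epithelial markers had 1 of 11 rising, KRT17 (0.52 ± 0.12), and 0 falling, as adjusted over the list alone (0.763), with a median of -0.02 and a mean of 0.05. KRT17 lost its call without control library 2 (0.0739), and KRT15 (-0.36) and SFN (-0.22) did not pass. Only 3 leukocyte markers, CD14 (-0.18), ITGAM (0.15) and CD8A (0.15), were tested, too few for a list test, and 0 changed by either adjustment, adjusted over the list alone included.

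Some measures linked to RNA composition separated the groups and others did not. Mitochondrially encoded genes took 6.29 ± 0.242% of reads in control and 7.12 ± 0.569% in withdrawal libraries (SD, n = 3; two-sided exact permutation p = 0.10, the smallest that 3 against 3 can give). Mitochondrial rRNA took 0.707 ± 0.0125% against 1.01 ± 0.143%, 45S rRNA 0.00244 ± 0.000147% against 0.00571 ± 0.00268%, long noncoding RNAs 0.758 ± 0.00890% against 0.789 ± 0.00515%, protein-coding genes 97.5 ± 0.0163% against 97.1 ± 0.149% and the 10 most abundant genes 9.67 ± 0.202% against 10.3 ± 0.133% (exact permutation p = 0.10 for each). Mitochondrial mRNA (5.55 ± 0.233% against 6.07 ± 0.562%), 7SL RNA (0.00298 ± 0.00103% against 0.00785 ± 0.00443%) and pseudogenes (0.733 ± 0.0103% against 0.767 ± 0.0424%) overlapped between the groups (exact permutation p = 0.300 for each). Of the 13 mitochondrial mRNAs MT-ND3 (0.37 ± 0.08) and MT-ND2 (0.38 ± 0.09) rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0698). MT-ND1 (0.20) passed only without withdrawal library 2 (0.0105). MT-ND2 has a nuclear pseudogene copy and lost its call without control library 3 (0.0564), and the list passed without control library 1 (0.0417) or withdrawal library 2 (0.00195). Cytosolic ribosomal protein genes had 1 of 38 rising, RPS23 (0.75 ± 0.16), and 0 falling, as adjusted over the list alone (0.527), and passed without withdrawal library 3 (0.00215), as did RPL30 (0.22; 0.00504 without that library), while RPL7 (0.24) did not pass. Small nucleolar RNA host genes had 1 of 14 rising, SNHG16, and 0 falling, as adjusted over the list alone (0.590); SNHG16 lost its call without control library 1 (0.119), 2 (0.128) or 3 (0.0941) or withdrawal library 1 (0.0617), and SNHG15 (0.19) and SNHG6 (0.17) did not pass. Nuclear-retained long noncoding RNAs had 2 of 7 falling and 0 rising (2 and 1 adjusted over the list alone; 0.425), FTX (-0.56 ± 0.14) and NEAT1 (-0.35 ± 0.09). FTX lost its call without control library 2 (0.0726) or 3 (0.0739), and NEAT1 without control library 2 (0.124) or 3 (0.107), while NORAD (0.22) did not pass. The genes called lower were richer in GC, with a median of 58.1% against 46.5% for those called higher and 50.5% for all tested genes. A slope on GC was fitted to each library's deviation from the gene's mean log2 CPM over all libraries. In log2 units per 10 percentage points it was 0.0553 ± 0.0586 in control and -0.0553 ± 0.0998 in withdrawal libraries (exact permutation p = 0.300). The group means mirror each other by construction, so of the 2 means only their difference carries information. By library the slopes were 0.0260, 0.123 and 0.0171 in control libraries 1, 2 and 3. In withdrawal libraries 1, 2 and 3 they were 0.0503, -0.0681 and -0.148, so withdrawal library 1 lay within the control range. With the GC offset the calls of HMGCR (adjusted p = 0.0910), FASN (0.104), CRY1 (0.181), PLK1 (0.0725), MT-ND2 (0.0559), MT-ND3 (0.129) and UQCRB (0.336) ended, while CDKN1A (0.00222), the mitosis list (0.00106, lower) and the nuclear-retained RNA list (0.0263) passed. The DESeq2 Wald test ended the calls of RPS23 (0.0640), PLIN2 (0.0624) and H2BC11 (0.0597), limma-voom that of PER2 (0.0667) and library totals alone that of CRY1 (0.0527), while the stricter filter let the histone list pass (0.00825). Withdrawal libraries also differed more from one another, with a chi-square per gene of 10.6 to 18.5 between pairs, against 2.70 to 4.32 between control libraries and 12.05 to 25.3 across the groups.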

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

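Named genes and lists kept their direction under the planned settings that use all libraries and under the 3 added after seeing the data, apart from the list reversals given here, none of which passed the threshold. The counts called higher and lower stayed within 1.5 times of 894 and 842 in all of those settings. The stricter filter, which tests 10292 genes and drops 100 of the 2-fold higher and 42 of the 2-fold lower calls by construction, gave 68 genes at least 2-fold higher and 23 lower, and the DESeq2 Wald test gave 109 higher (the cause was not tested). An estimated correlation gave 0 lists higher and 0 lower by limma camera, against 8 and 5 with the preset one, with 6 at an unadjusted p under 0.05; fry, which sets no list against other genes, gave 11 and 6. Leaving out 1 library at a time gave 410 to 1004 genes higher, 291 to 938 lower, 122 to 165 at least 2-fold higher, 38 to 81 at least 2-fold lower, 7 to 11 lists higher and 3 to 6 lower. The lowest gene counts came without control library 2 and the 3 lists without withdrawal library 1. In all 6 of these fits 336 genes were called higher and 265 lower, and under every one of 17 alternatives 288 and 248 were. The labels do not say whether a replicate number is shared between the groups. Deviations of same-numbered libraries correlated at -0.00499, -0.00322 and 0.0642, and of the 6 libraries only those numbered 3 correlated best with each other. These values show little shared deviation, but with 3 libraries per group they cannot exclude pairing. With the replicate block 990 genes were higher and 928 lower (882 and 816 shared with 894 and 842), with 7 lists higher and 5 lower, and the serine list had an adjusted p of 0.0767. Direction turned for the fatty acid synthesis list with the stricter filter (0.891), the block (0.972) and the GC offset (0.867), the basal list with the stricter filter (0.813), and the hexosamine and small nucleolar RNA host lists with the GC offset (0.867 each). Leaving out 1 library also turned, in at least 1 of the 6 fits and never past the threshold (ranges are over all 6 fits, turned or not), fatty acid synthesis (0.552 to 0.916), basal (0.492 to 0.979), pentose phosphate (0.472 to 0.993), ribosomal proteins (0.00215 to 0.791), small nucleolar RNA hosts (0.111 to 0.760) and oxidative phosphorylation (0.0290 to 0.626), where 0.00215 and 0.0290 came from fits that kept the direction, and the log2 fold changes of ITGAM (-0.0764 to 0.311) and FN1 (-0.272 to 0.0370). The cause of these turns was not tested. At this depth and number of libraries the simulation recovered 59.7% of 1.5-fold changes; depth and replicate number were not varied.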

Other observations

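Some changes prompted a look at gene groups other than the lists fixed beforehand, with AHR, MT2A, SLC30A1, CCN2 and AMOTL2 chosen after their values were seen and the other genes of these groups taken from lists drawn up before their values were looked at. AHR, the aryl hydrocarbon receptor, rose by 0.82 ± 0.14 on the log2 scale (edgeR adjusted p = 8.19e-04), as did AHRR, its repressor, by 0.94 ± 0.14, TIPARP by 0.87 ± 0.13, NFE2L2, which encodes NRF2, by 0.90 ± 0.12 and EREG, a growth factor gene, by 1.67 ± 0.34. Among metal-handling genes, the metallothionein gene MT2A rose from 164 to 289 CPM (0.81 ± 0.09, adjusted p = 2.47e-05) and the zinc exporter gene SLC30A1 by 0.84 ± 0.11. Of 4 other metal-responsive genes, too few for a list test under the minimum of 5 tested genes, 3 rose, HSPA6 by 1.39, MT1F by 0.52 and MT1X by 0.75. SLC39A10 (0.44, adjusted p = 0.189) did not pass, and 4 rose adjusted over the list alone. Metallothionein genes resemble one another and can divide reads. MT1X lost its call without control library 2 (adjusted p = 0.134) or 3 (0.0973) or withdrawal library 1 (0.121) or 2 (0.102).

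Among genes that respond to YAP and TEAD, the effectors of the Hippo pathway, CCN2 rose by 2.03 ± 0.27 and AMOTL2 by 0.74 ± 0.09; CCN2 and CCN1 also belong to the AP-1 and immediate-early list fixed beforehand. Of 14 others 4 rose and 0 fell, and the same numbers held adjusted over the list alone. ANKRD1 rose by 2.82 ± 0.43 from only 0.318 CPM, CRIM1 by 0.49 ± 0.11, CCN1 by 0.52 ± 0.12 and NUAK2 by 0.39 ± 0.12. CRIM1 lost its call without control library 1 (0.0690), CCN1 without control library 1 (0.0537) or 2 (0.0545), and NUAK2 without any library but withdrawal library 2 (0.117, 0.142 and 0.166 without controls 1, 2 and 3, and 0.0686 and 0.0987 without withdrawals 1 and 3). Of 56 gene families grouped by symbol prefix, a grouping made after the data were seen, the CYP genes alone passed camera without a GC offset (27 tested, 5 rose, 0 fell; limma adjusted p = 0.0172, and adjusted p = 0.984 with an estimated correlation). With the GC offset the CYP (adjusted p = 0.0138, higher), KRT (0.0112, higher), DUSP (0.0258, higher) and SEC (0.0258, lower) families passed camera with the preset correlation. Without the offset KRT, DUSP and SEC had camera adjusted p of 0.517, 0.189 and 0.586, and 0.984 each with an estimated correlation. An estimated correlation was not run with the offset. The CYP family includes CYP1A1, CYP1B1 and CYP1B1-AS1, so its test restates their rise in part.

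The tests chosen only after the result was seen were the splits of the libraries, the gene families, the median of the genes called lower with the GC offset, and the extra medium change; the offsets for GC and length and the 3 added lists were also chosen after seeing the data, with the prediction written before each was run. A first hypothesis concerns CYP1A1 and CYP1B1: aryl hydrocarbon receptor activity may have risen in the withdrawal cells. Of 10 other targets of the receptor 8 rose and 0 fell, with a median log2 fold change of 0.63, and limma camera with an estimated correlation gave p = 0.00581 (adjusted over 3 such lists 0.0174), while NQO1 (0.15) and UGT1A6 (0.04) did not pass and ALDH3A1 lost its call without control library 2 (adjusted p = 0.105) or 3 (0.0593) or withdrawal library 1 (0.0612). The list was drawn up after CYP1A1 and CYP1B1 were seen to rise, and it shares SLC7A5 and NQO1 with lists fixed beforehand. Its adjusted p cannot be set beside those of the lists fixed beforehand, which were adjusted over 35 lists. Among these the integrated stress response had a smaller unadjusted p by the same camera test (0.00170) and did not pass (adjusted p = 0.0596). By limma camera with an estimated correlation the metal-responsive list gave p = 0.0295 (adjusted over the 3 lists 0.0443), but with 4 genes it is below the minimum and decides nothing. The YAP and TEAD list gave 0.265 both before and after that adjustment, and 0.0139 both before and after it with the preset correlation, which leaves that hypothesis open. What stimulus lies behind any of these cannot be told apart from an additional medium change in the withdrawal group, since 0 arms had a second change into medium with glucose.

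The genes called lower were GC-rich, and a GC-content bias between libraries could produce such a pattern. An offset for GC content kept 79.9% of them (673 of 842), just under the 80% fixed as the bound against this explanation, and an offset for transcript length kept 98.0%, which argues against length as the cause. Over all 842 the median log2 fold change was -0.50 ± 0.11 (median SE of single genes) before and -0.44 ± 0.10 with the offset. These genes were selected as lower in the same data, so their median cannot decide whether a GC trend was the whole cause. The trend that the offset removes does not account for the 673 calls kept. For the 169 whose calls ended the median went from -0.36 ± 0.11 to -0.26 ± 0.10, so the fold shrank. How far a GC bias was part of the cause stays open, since the share kept was under that bound. GC content also bears on the genes called higher, of which the offset kept 753 of 894, among 1012 called higher with it. Over all genes with a GC value the Spearman correlation of log2 fold change with GC was -0.308. The offset also lowered the common biological coefficient of variation from 0.0985 to 0.0834, which helps calls pass. A biological link between GC content and withdrawal stays open as untested.

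A pair of large changes came with near-identical gene copies, among which reads can be divided. BOLA2B stood at -3.68 on the log2 scale because control library 3 held 54.7 CPM against 0.656 to 2.45 CPM in the other 5 libraries, and without it the adjusted p was 0.641; without withdrawal library 1, 2 or 3 it was 0.0795, 0.0812 and 0.0769. Summed with BOLA2 the change was -3.61 ± 1.01, so division of counted reads between the copies does not account for it. Reads with several matches may be missing from both copies, since their handling is not given, and the sum cannot cover these. No biological explanation was tested for a value found in 1 control library. EIF3CL rose by 2.11 ± 0.53 with 14.6, 60.0 and 4.89 CPM in the withdrawal libraries, and its adjusted p was 0.189 without withdrawal library 2 and 0.0784 without control library 2. Summed with EIF3C the change was 0.69 ± 0.24 (adjusted p = 0.0711), within 1 SE of the 0.5 set as the bound, so division of reads could still contribute.

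Of the 10 ways to split the 6 libraries 3 against 3, 1 (the real one) called as many genes, with 1736 by edgeR against 0 in the highest other split. In the other splits 178 to 747 genes had an unadjusted p under 0.05, and 3781 did in the real split. Every other split put libraries of both groups on each side, so most of the group difference became spread within its sides. That held their gene counts down, so these counts do not measure calls made without a group difference. For genes at least 2-fold changed the real split gave 232 against 0, again as 1 of 10. For lists past the camera threshold with a preset correlation it gave 13 against 9 in the highest other split. The other splits, in which 0 genes were called, gave 2, 5, 6, 0, 9, 5, 7, 7 and 0 lists. With a preset correlation camera thus passed lists in most splits other than the real one, which limits what the 13 lists show. Those splits still held part of the group difference, so they do not show how often lists pass without one. With 10 splits no share under 0.05 can be reached.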
